A study of Homo sapiens with 12 samples.

How the data were processed

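The series holds 12 stranded mRNA-seq libraries of MCF7 and MDA-MB-231 cells, in 4 groups of 3: each line with products of activated or isotype-treated PBMC. Per the labels' protocols, 3 M PBMC in medium with 10% serum were treated for 48 h, and the cancer cells were exposed for 24 h across 0.4 µm inserts, to conditioned medium, or to both. The library titles give the formats as PBMC, as an abbreviation, and as PBMC plus that abbreviation. The abbreviation is not spelled out and was read as conditioned medium, the remaining exposure in the protocols. The PBMC came from human blood donors, whose data are not described. The libraries share no replicate numbers in the labels, nothing says they came from separate cultures, and the 3 formats within a group served as replicates 1 (conditioned medium), 2 (PBMC) and 3 (PBMC plus conditioned medium).

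The authors deposited 1 table of 56764 genes by 12 libraries, with an Ensembl identifier and a symbol per row. Its values are log2 expression as deposited by the authors: from the values themselves, gene read numbers had been divided by a size factor and variance-stabilized, so that 0 reads is 0.002 and high values approach the log2 of the normalized count. Per the submitters' processing notes, TopHat2 2.0.8b, bedtools 2.16.2, featureCounts 1.4.6, DESeq 1.10.1 and the hg19 build were used; the role and settings of each are not given in the sources used here, and neither is whether counting used strand. The annotation at hand was GENCODE 29 on another build, so it gave no coordinates and served only to find the genes left out. A total of 463 rows, those of the Y chromosome and XIST, were left out of every step, leaving 56301.

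Inverting the transform gave whole reads: all 169487 values under 200 reads lay within 0.1 of a whole number. The size factors were 0.736 to 1.546 and the depth was 21.0 to 44.8 M reads per library. Floors and intervals from reads cover counting error only. Library pairs of 1 group differed by chi-square per degree of freedom of 3.6 to 197.7. The smallest was between the MDA-MB-231 isotype libraries with PBMC and PBMC plus conditioned medium, where the median over genes was 1.23. No pair was counted as 1 sample, but a difference beyond counting error does not show that libraries came from separate cultures.

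Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on the deposited log2 values. The design fixed before the data were examined foresaw log2(value + 1) for normalized values; since the deposited values were already on a log2 scale they were used directly, and the form in the design was run as an alternative added after the values were seen. Genes needed a normalized count of at least 10 in at least 3 libraries, a filter chosen after the table was seen and before any test, which left 18453. The model had 6 line-by-format levels and 1 activation term per line, with 4 residual and 3.59 prior degrees of freedom, and all 12 libraries shared 1 spread. Its contrasts were activation in each line, their difference (MDA-MB-231 minus MCF7), the lines under isotype, and the formats. A second model added activation by format, as an effect shared by both lines. P-values were two-sided and adjusted by Benjamini-Hochberg at 0.05. Log2 differences understate the change of genes near 0 reads.

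A total of 28 lists fixed before the data were examined (487 genes, 421 tested) were tested with camera (correlation preset at 0.01, then estimated) and fry: tryptophan-kynurenine pathway, interferon-gamma response, MHC class I and II, type I interferon-stimulated genes, NF-kappaB and TNF targets, chemokines, immune checkpoint ligands, JAK-STAT, estrogen response, cell cycle, cell death, complement, epithelial-mesenchymal genes, DNA methylation machinery, hypoxia and glycolysis, amino acid and ER stress, cholesterol synthesis, luminal and mesenchymal markers, 6 sets of blood cell markers, T cell cytokines and reference genes. Named genes followed a fixed rule: the 10 largest rises and 5 largest falls that passed with 1 sign in all 3 formats, all measured kynurenine genes, up to 4 members per list by adjusted p, ESR1, GATA3 and VIM, and for the lines and formats the 5 largest differences each way. Genes named in the account of blood cell transcripts and of single libraries were chosen after their values were seen.

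On simulated data with 200 changed genes among 18453, the test recovered 26% of log2 changes of 1 and 58% of changes of 2 for MCF7 (7 false of 91 calls), 39% and 77% for MDA-MB-231 (6 of 122) and 9% and 44% for the difference (3 of 56). Both lines were simulated with the same spread per gene, so their unlike rates do not show unlike power. The data had far more called genes than the 200 simulated, so these rates need not hold there. Alternatives were quantile normalization, equal library totals, no filter, a filter of 50, added constants of 0.5, 1 and 5, each line alone, no format block, a test against a fold change of 2, voom on the recovered reads, and leaving out each pair of libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.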

Results

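The series asked how soluble products of activated human T cells change gene expression in 2 breast cancer lines, with attention to IDO1, the enzyme that starts tryptophan breakdown along the kynurenine pathway. MCF7 is a luminal, estrogen receptor-positive line and MDA-MB-231 a mesenchymal, estrogen receptor-negative line. Peripheral blood mononuclear cells (PBMC) had been stimulated for 48 h with anti-CD3 and anti-CD28 antibodies, which activate T cells, or kept with isotype control antibodies. The cancer cells were then exposed for 24 h to one of 3 formats: the conditioned medium, the PBMC behind a 0.4 µm insert that prevents contact, or PBMC plus conditioned medium. The 12 RNA-seq libraries form 4 groups of 3 (line by antibody), with 1 library per line, antibody and format. No library was repeated, so the 3 formats took the place of replicates. Every SE and p-value of the main model rests on how the activated-minus-isotype difference varied between formats. This holds for the comparison of the lines under isotype too, whose SE thus draws on the activated libraries as well. Each SE uses 1 spread per gene, shared by both lines and drawn toward a trend over all genes. It is therefore not the spread of 1 line alone. The deposited values are variance-stabilized log2 expression. The recovered depth was 21.0 to 44.8 M reads per library, with a mean of 31.0 M, and 18453 genes were tested.

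Under isotype control the lines differed as their labels state. MSN (moesin, a membrane-cytoskeleton linker), GPR116, FLNC, PTPRM and SRGN were the genes most elevated in MDA-MB-231, with log2 differences of 15.32 for MSN and 12.38 for SRGN at the ends of the range. SULF2, DSCAM-AS1, SPTSSB, FXYD3 and CACNG4 were the genes most elevated in MCF7, with log2 differences (MDA-MB-231 minus MCF7) of -15.45 for SULF2 and -12.36 for CACNG4. ESR1, which encodes the estrogen receptor, averaged 13.43 in MCF7 and 1.92 in MDA-MB-231, a difference of -11.51 ± 0.84 (SE; limma adjusted p = 1.14e-05). The luminal factor GATA3 differed by -6.87 ± 0.14 and the mesenchymal filament gene VIM by 9.39 ± 0.27. All 14 luminal markers were lower and all 14 mesenchymal and basal-like markers were higher in MDA-MB-231. In total 12779 genes differed, 6357 higher and 6422 lower in MDA-MB-231.

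In MCF7 the largest rises after activation were in the chemokine genes CXCL11 (10.99 ± 0.57 log2, limma adjusted p = 1.67e-05) and CXCL10 (10.98 ± 0.30). Values are mean differences over 3 formats ± SE, with the SE from the spread shared by both lines. Next came CD74, the MHC class II invariant chain (10.45 ± 0.20), GBP1 (10.44 ± 0.21), IDO1 (10.26 ± 0.80) and CXCL9 (10.21 ± 0.73). After these ranked HLA-DQA1 (10.15 ± 0.44), S100A7A (10.14 ± 0.71), HLA-DPA1 (9.99 ± 0.14) and GBP1P1 (9.66 ± 0.26). GBP1P1 is a pseudogene of GBP1, S100A7A is a close copy of S100A7, and HLA genes resemble one another, so reads may have been shared within these families. The largest falls were in KCNJ8, a potassium channel gene (-6.66 ± 0.93, adjusted p = 0.00225), KLHL4 (-5.41 ± 0.95), RP11-662G23.1 (-5.28 ± 0.76), RP11-13L2.4 (-5.26 ± 0.70) and C10orf107 (-4.80 ± 0.42). Of 6506 genes changed, 3333 rose and 3173 fell. Rises were larger: 299 genes rose and 24 fell over 16-fold on this scale. The count was 2075 without the conditioned medium pair, 2235 without the PBMC pair, 3973 with MCF7 fitted alone and 838 when tested against a fold change of 2. With every library scaled to the same total, 2412 of 7450 changed genes rose (32.4%, against 51.2%), because that scaling moved the median of all genes from -0.02 to -0.26.

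All 30 genes of the interferon-gamma response list rose in MCF7, with a median of 6.61 log2. Examples were CIITA, the MHC class II transactivator (7.95 ± 0.19), PARP14 (5.51 ± 0.11) and APOL6 (6.64 ± 0.18). All 18 genes of antigen processing and MHC class I rose, among them the immunoproteasome subunits PSMB8 (5.95 ± 0.11) and PSMB9 (7.20 ± 0.15) and the peptide transporter TAP1 (7.03 ± 0.17). All 14 MHC class II genes rose, with HLA-DRA at 8.73 ± 0.13, as did 32 of 33 type I interferon-stimulated genes, including IFI44L (8.04 ± 0.20), OAS2 (7.34 ± 0.21) and IFIT3 (7.83 ± 0.23). Of 30 NF-kappaB and TNF targets 26 rose, with SOD2 at 5.36 ± 0.35 and BIRC3 at 6.27 ± 0.42. Among 17 chemokine genes 13 rose and CXCL12 fell (-3.10 ± 0.45). Complement genes rose in 13 of 14 (C1S 8.47 ± 0.19, CFB 8.18 ± 0.47), cell death genes in 20 of 24 (CASP10 5.69 ± 0.28, TNFSF10 5.11 ± 0.32) and JAK-STAT pathway and feedback genes in 19 of 24, with 2 falls (STAT1 4.20 ± 0.12, SOCS1 4.09 ± 0.26). Of 15 immune checkpoint ligand genes 9 rose and 1 fell, led by CD274, which encodes PD-L1 (8.02 ± 0.38, adjusted p = 1.04e-05).

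Proliferation genes moved the other way in MCF7. Of 30 cell cycle and DNA replication genes 29 fell, with a median of -1.69 log2, for example TK1 (-1.70 ± 0.26) and AURKB (-2.08 ± 0.33). Hypoxia and glycolysis genes rose in 18 of 22 (ADM 3.18 ± 0.34, VEGFA 2.86 ± 0.45), cholesterol synthesis genes in 10 of 18 (MVD 1.60 ± 0.18) and amino acid and ER stress response genes in 8 of 21, with 2 falls (ATF3 3.64 ± 0.45). Epithelial-mesenchymal genes were split, with 9 rises and 2 falls among 20 (FN1 3.60 ± 0.41, ZEB1 1.99 ± 0.22). Of 11 monocyte and macrophage markers 8 rose, among them S100A8 (8.99 ± 0.49), S100A9 (7.77 ± 0.64) and FCGR3A (5.69 ± 0.38), while the leukocyte marker PTPRC had 0 reads in all 6 MCF7 libraries. Of 9 measured tryptophan-kynurenine genes 5 rose and 2 fell. Camera with a preset correlation placed these 17 lists past its adjusted threshold. Fry, which asks whether a list moved at all, called all of these but amino acid and ER stress (adjusted p = 0.148). Its adjusted p was 7.99e-05 for interferon-gamma and 0.0456 for cell cycle. With camera and an estimated correlation 1 list, MHC class II, passed (adjusted p = 0.025). The other lists then had adjusted p = 0.195 (interferon-gamma, MHC class I, type I interferon, complement, monocyte), 0.278 (chemokines), 0.283 (cell death), 0.366 (NF-kappaB, checkpoint, JAK-STAT, cholesterol, epithelial-mesenchymal and kynurenine lists), 0.368 (hypoxia), 0.378 (cell cycle) and 0.604 (amino acid and ER stress). Adjusted over the list alone, the counts of rises changed to 33 for type I interferon genes, 14 for chemokines, 21 for cell death, 19 for hypoxia and 13 for cholesterol synthesis, and the checkpoint list had 2 falls.

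**Figure D1:**
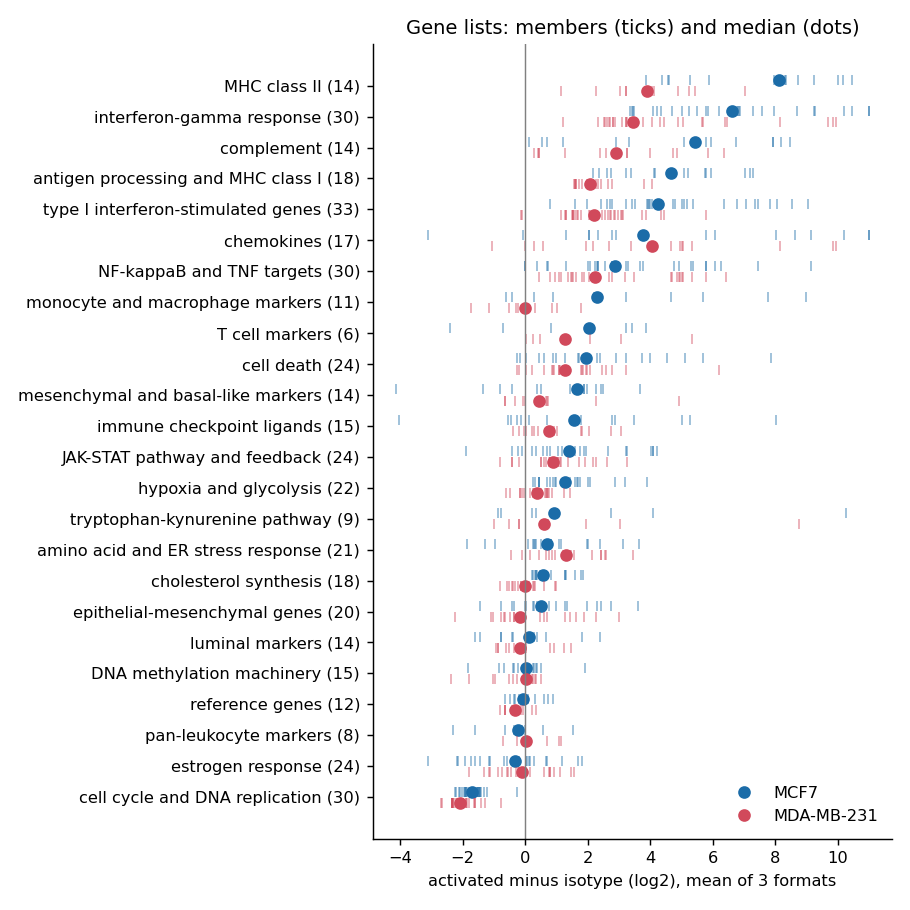
Activated minus isotype log2 difference (horizontal axis, mean of 3 formats) for the gene lists with at least 5 tested genes, in MCF7 (blue) and MDA-MB-231 (red). Ticks are genes, dots are list medians and the number of tested genes is in brackets. The MHC class II median was 8.13 in MCF7 and 3.90 in MDA-MB-231, and the cell cycle median was -1.69 and -2.10.

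In MDA-MB-231 the largest rises were in CXCL9 (9.94 ± 0.73 log2; limma adjusted p = 0.000358), CXCL10 (9.84 ± 0.30), GBP5 (9.70 ± 0.55), LGALS17A (8.76 ± 0.62), IDO1 (8.76 ± 0.80), CXCL11 (8.15 ± 0.57), IRG1, which makes itaconate (7.99 ± 1.01), TNFAIP6 (7.93 ± 0.79), SLAMF8 (7.50 ± 0.59) and GBP1P1 (7.34 ± 0.26). TNFAIP6 had no reads in the isotype libraries, and its mean normalized count was at least 128.6-fold higher after activation, against a floor of 3 reads per library. This floor takes reads as independent. The largest falls were in ZNF488 (-5.35 ± 0.90), DMBT1 (-4.50 ± 0.49), the water channel gene AQP5 (-4.47 ± 0.54), NGFR (-4.36 ± 0.60) and AC011738.4 (-4.31 ± 0.53). Of 4892 genes changed, 2497 rose and 2395 fell, and 87 rose over 16-fold. This count rested on the joint fit with MCF7: MDA-MB-231 fitted alone gave 66 genes, of which 64 rose. The median residual SD was 0.242 in MDA-MB-231 alone and 0.273 in the joint fit, so it was not smaller in the joint fit. What lowered the count was not tested. It was 562 without the PBMC plus conditioned medium pair, 2005 without the conditioned medium pair, which held blood cell transcripts, and 235 against a fold change of 2. With equal library totals 1840 of 4955 changed genes rose (37.1%, against 51.0%), as the median of all genes moved from 0.00 to -0.14.

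Of the interferon-gamma response genes 29 of 30 rose in MDA-MB-231, with a median of 3.44 log2, including ETV7 (6.40 ± 0.21) and STAT1 (3.27 ± 0.12). All 18 MHC class I genes rose (TAP1 3.79 ± 0.17), as did 13 of 14 MHC class II genes (HLA-DRA 4.13 ± 0.13, HLA-DQB1 4.89 ± 0.17), 31 of 33 type I interferon-stimulated genes (IFI44L 5.77 ± 0.20), 25 of 30 NF-kappaB and TNF targets (SOD2 4.69 ± 0.35, PTGS2 4.84 ± 0.54), 11 of 17 chemokines, 12 of 14 complement genes (C1S 5.85 ± 0.19, SERPING1 6.36 ± 0.50), 19 of 24 cell death genes (BCL2A1 6.21 ± 0.68), 16 of 24 JAK-STAT genes, with 2 falls, and 7 of 15 checkpoint genes (LGALS9 3.07 ± 0.38, PDCD1LG2 2.76 ± 0.37). All 30 cell cycle genes fell, with a median of -2.10 (PLK1 -2.65 ± 0.44). Amino acid and ER stress genes rose in 13 of 21 and fell in 1 (HSPA5 1.21 ± 0.12, HERPUD1 1.29 ± 0.14). Hypoxia and glycolysis genes rose in 5 of 22, and 4 of 12 reference genes fell (SDHA -0.65 ± 0.10). The hypoxia rises numbered 3, with 1 fall, under quantile normalization and 2 with equal library totals. Fry called all of these 14 lists but amino acid and ER stress (adjusted p = 0.051) and hypoxia (0.434). All 14 passed camera with a preset correlation. With an estimated correlation 1 list, MHC class II, passed (adjusted p = 0.0313), and the others had adjusted p = 0.245 (interferon-gamma, MHC class I, type I interferon, chemokine, complement and reference lists), 0.311 (NF-kappaB, cell death), 0.372 (checkpoint, JAK-STAT, cell cycle), 0.38 (amino acid and ER stress) and 0.763 (hypoxia). Adjusted over the list alone, rises were 14 for MHC class II, 27 for NF-kappaB, 12 for chemokines, 19 for JAK-STAT, 20 for cell death with 1 fall, 14 for amino acid and ER stress, and 1 each for hypoxia and the reference genes.

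Several lists passed camera in neither line. Fry called some lists that camera did not. In MCF7 these were the mesenchymal markers (adjusted p = 0.0191) and the platelet list of 1 tested gene (0.0103). In MDA-MB-231 they were the DNA methylation (fry adjusted p = 0.00882), T cell (0.0209), T cell cytokine (0.0058) and kynurenine lists (0.0186). The 24 estrogen response genes had 4 rises and 7 falls in MCF7 (MYB -2.18 ± 0.40, STC2 -2.15 ± 0.45). In MDA-MB-231 they had 5 rises and 3 falls. With equal library totals there were 3 rises and 9 falls in MCF7, and 4 rises and 6 falls in MDA-MB-231. Among 15 genes of the DNA methylation machinery, 2 rose and 3 fell in MCF7 and 5 fell in MDA-MB-231. The maintenance methyltransferase DNMT1 changed by -0.69 ± 0.18 in MCF7 (adjusted p = 0.0211) and -1.03 ± 0.18 in MDA-MB-231 (adjusted p = 0.00782), and its partner UHRF1 by -1.82 ± 0.40 in MCF7. Luminal markers had 3 rises and 1 fall among 14 in MCF7 and 3 rises and 3 falls in MDA-MB-231. Mesenchymal and basal-like markers had 8 rises and 3 falls among 14 in MCF7 (MSN 2.26 ± 0.18, CAV1 -4.12 ± 0.40) and 2 rises in MDA-MB-231. Of the blood cell lists, 6 of 17 T cell markers, 8 of 12 pan-leukocyte, 1 of 10 NK cell, 2 of 8 B cell, 1 of 8 platelet and red cell markers and 2 of 15 T cell cytokines were expressed highly enough to test. In MCF7 the T cell list had 3 rises and 1 fall, the pan-leukocyte list 1 rise and 2 falls, the cytokine list 1 rise (TNF 4.77 ± 0.74), the platelet list 1 fall and the NK and B cell lists 0 changes. In MDA-MB-231, whose conditioned medium library with activation held T cell transcripts (55 reads of CD2 and 53 of CD3E), the T cell list had 2 rises (ITK 5.32 ± 0.77, with differences of 4.12 for conditioned medium, 3.73 for PBMC and 8.11 for both), the pan-leukocyte list 1 rise and 1 fall, the cytokine list 1 rise (CSF2 2.85 ± 0.29), and the NK, B cell and platelet lists 0 changes. The kynurenine list had 4 rises and 1 fall in MDA-MB-231, the cholesterol list 2 rises and 1 fall, the epithelial-mesenchymal list 5 rises and 3 falls, and the monocyte list 1 rise and 1 fall. The 12 reference genes had 3 rises and 3 falls in MCF7, and 1 rise and 4 falls there under quantile normalization. Adjusted over the list alone, MCF7 had 5 rises among the estrogen response genes and 4 among the reference genes, and MDA-MB-231 had 1 rise and 6 falls among the DNA methylation genes and 1 rise among the B cell markers.

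The responses of the lines overlapped. There were 1203 genes that rose in both lines (451 if the lists were independent) and 981 that fell in both (412 if independent), while 113 rose in MCF7 and fell in MDA-MB-231 and 120 did the opposite (433 and 429 if independent). The calls of both lines use the same spread per gene, so they are not independent even without a shared response. The numbers for independence are thus only a rough baseline. Across genes, which are not independent replicates, the log2 changes of the lines had a Pearson correlation of 0.49.

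By the test of the difference between the responses, single genes of antigen presentation and the interferon response rose more in MCF7, while 0 lists passed with an estimated correlation. CD74 rose by 7.23 log2 less in MDA-MB-231 (-7.23 ± 0.28; limma adjusted p = 8.28e-05), HLA-DPA1 differed by -6.11 ± 0.20, HLA-DRA by -4.59 ± 0.18, PSMB9 by -4.78 ± 0.21, IFIT3 by -5.78 ± 0.32 and GBP1 by -5.55 ± 0.29. The activated levels of these genes were closer than their isotype levels. CD74 averaged 4.66 in MCF7 and 12.14 in MDA-MB-231 under isotype, and 15.11 and 15.36 after activation. Over the 14 MHC class II genes the median level difference, MDA-MB-231 minus MCF7, was 4.52 under isotype and 0.26 after activation, and over the interferon-gamma list it was 2.67 and 0.24. CD274 showed this too: it averaged 3.29 in MCF7 and 10.70 in MDA-MB-231 under isotype, and 11.31 and 12.51 after activation, so its responses differed by -6.21 ± 0.53 (adjusted p = 0.00134).

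The 10 largest upward and 5 largest downward differences came from genes that responded in 1 line or in opposite directions. S100A7A (-10.14 ± 1.01), the calprotectin subunits S100A8 (-8.99 ± 0.70) and S100A9 (-8.95 ± 0.91), S100A7 (-8.46 ± 0.69) and TMEM98 (-8.37 ± 0.79) favoured MCF7, and S100A8 had 0 reads in all 6 MDA-MB-231 libraries. IRG1 (7.99 ± 1.43), SERPINB2 (7.07 ± 1.07), SLAMF8 (6.94 ± 0.83), and FAM20A (5.23 ± 0.87) rose in MDA-MB-231 and did not pass in MCF7. ATP8A2 (5.57 ± 0.60) and SCG5 (5.48 ± 0.89) rose in MDA-MB-231 and fell in MCF7. KCNJ8 (6.59 ± 1.32), RP11-13L2.4 (5.26 ± 0.98), RP11-662G23.1 (5.23 ± 1.07) and C10orf107 (5.18 ± 0.60) fell in MCF7 and did not pass in MDA-MB-231. In total 2512 genes differed, 1115 higher and 1397 lower in MDA-MB-231, of which 226 rose in both lines, 10 fell in both and 233 were called in opposite directions. The count was 447 without the MCF7 conditioned medium pair, 575 without the MCF7 PBMC pair, 1128 without the MDA-MB-231 conditioned medium pair, 448 without the MDA-MB-231 PBMC plus conditioned medium pair and 196 against a fold change of 2.

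By list, members with a lower response in MDA-MB-231 numbered 17 of 30 for interferon-gamma, 17 of 18 for MHC class I, 10 of 14 for MHC class II, with 1 higher, 24 of 33 for type I interferon genes, 6 of 14 for complement (C4A -4.50 ± 0.44, which its copy C4B may share reads with), 5 of 24 for cell death (CASP10 -3.90 ± 0.39), 9 of 24 for JAK-STAT, with 2 higher (STAT3 -1.09 ± 0.13, JAK1 0.91 ± 0.14), 5 of 22 for hypoxia and glycolysis (ADM -2.46 ± 0.48), 5 of 18 for cholesterol synthesis (DHCR24 -1.65 ± 0.25) and 6 of 11 for monocyte markers (FCGR3A -5.69 ± 0.54). These 10 lists passed camera with a preset correlation and 0 passed with an estimated one, where adjusted p = 0.083 for MHC class II, 0.261 for MHC class I and monocyte markers, 0.38 for type I interferon, 0.464 for interferon-gamma, 0.542 for complement, 0.598 for cholesterol synthesis and 0.732 for JAK-STAT, cell death and hypoxia. Adjusted over the list alone, lower responses numbered 21, 18, 12, 27, 8, 10, 11, 10, 10 and 7 in the order given. Of the 10 lists, fry called interferon-gamma, MHC class I, MHC class II, type I interferon, complement and monocyte markers. The highest fry adjusted p among these was 0.0319, for complement. It also called the reference genes (fry adjusted p = 0.0182). The cell cycle list had 0 members that differed.

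IDO1, the gene of the series title, had 0 reads in each of the 3 MCF7 isotype libraries, at 21.0 to 29.5 M reads. After activation its value in MCF7 was 11.74 with conditioned medium, 11.73 with PBMC and 7.30 with PBMC plus conditioned medium (3113, 4488 and 240 reads), a mean of 10.26 ± 2.56 (SD, n = 3). Against a floor of 3 reads per isotype library, which takes reads as independent, its mean normalized count was at least 733.4-fold higher. In MDA-MB-231 IDO1 was present under isotype, at 100, 30 and 26 reads, and averaged 5.44 ± 0.80 (SD, n = 3), with 14.20 ± 0.55 after activation (16040, 12113 and 22344 reads). It rose in 3 of 3 formats in each line, by 10.26 ± 0.80 in MCF7 (SE; limma adjusted p = 0.000149) and 8.76 ± 0.80 in MDA-MB-231 (adjusted p = 0.000909). The responses differed by -1.50 ± 1.14 (adjusted p = 0.407), which is not past the threshold. This difference depends on the value given to 0 reads and on 1 format: it was 0.71 (adjusted p = 0.687) on the log2 scale of normalized count plus 5 and -2.98 (adjusted p = 0.008) without the MCF7 PBMC plus conditioned medium pair, within a range of adjusted p = 0.008 to 1 over all alternatives. The level of IDO1 after activation was 3.94 ± 0.80 log2 higher in MDA-MB-231 (adjusted p = 0.00285), and 2.44 higher without the MCF7 PBMC plus conditioned medium pair (adjusted p = 0.000775), a comparison added after the isotype values had been seen.

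**Figure D2:**
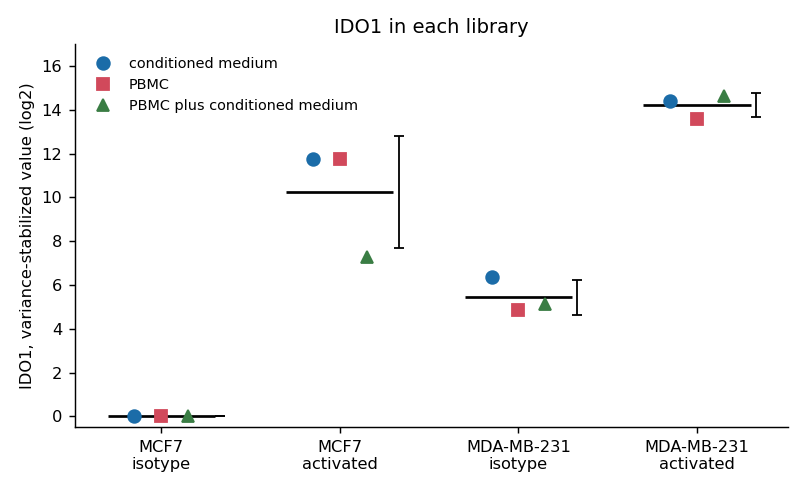
IDO1 variance-stabilized value (log2, vertical axis) in each of the 12 libraries by group. Symbols mark the exposure format, horizontal lines the group means and bars 1 SD (n = 3). The 3 MCF7 isotype libraries hold 0 reads, and the activated MCF7 library with PBMC plus conditioned medium (7.30) lies below the other activated MCF7 libraries (11.74 and 11.73).

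Downstream of IDO1, KYNU (kynureninase) rose by 2.76 ± 0.21 in MCF7 and 3.03 ± 0.21 in MDA-MB-231, and KMO (kynurenine 3-monooxygenase) by 4.09 ± 0.35 and 1.93 ± 0.35, with a difference between lines of -2.16 ± 0.50 (adjusted p = 0.0319). CCBL2 rose by 0.92 ± 0.14 and 0.61 ± 0.14. AADAT fell by 0.78 ± 0.25 in MCF7 and by 1.01 ± 0.25 in MDA-MB-231. CCBL1 changed by -0.86 ± 0.22 in MCF7 (adjusted p = 0.0196) and -0.53 ± 0.22 in MDA-MB-231 (adjusted p = 0.111), and QPRT by 1.02 ± 0.29 (adjusted p = 0.0314) and -0.20 ± 0.29 (adjusted p = 0.664). IDO2 and AFMID did not pass in either line, with 0.34 ± 0.34 and 0.22 ± 0.15 in MCF7 and 0.72 ± 0.34 and -0.21 ± 0.15 in MDA-MB-231.

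The exposure formats gave responses of unequal size, and the weak one was not the same in the 2 lines. In MCF7 the genes that rose over 2-fold had a median change of 2.20 log2 with conditioned medium, 2.32 with PBMC and 1.47 with PBMC plus conditioned medium. In MDA-MB-231 the corresponding medians were 1.93, 1.15 and 1.83. Falling genes had medians of -1.83, -1.88 and -0.97 in MCF7 and -1.97, -0.90 and -1.77 in MDA-MB-231. No gene passed limma for a format difference averaged over both lines, and voom on the recovered reads also called 0 in each comparison. At an unadjusted p under 0.05 there were 1062 genes for PBMC minus conditioned medium and 1449 for PBMC plus conditioned medium minus conditioned medium. For PBMC plus conditioned medium minus PBMC there were 436. The spread in this test holds the unlike activation responses of the formats. These 0 calls thus do not show that the formats were alike. The activation response depended on format alike in both lines in 0 genes (308 at an unadjusted p under 0.05, and 0 with voom). Without the MCF7 PBMC pair there were 137. A dependence that differed between the lines counted as residual spread, so this test could not show the unlike weak formats above. It had 2 residual degrees of freedom and recovered 33% of simulated shifts of 3 log2 set alike in both lines.

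**Figure D3:**
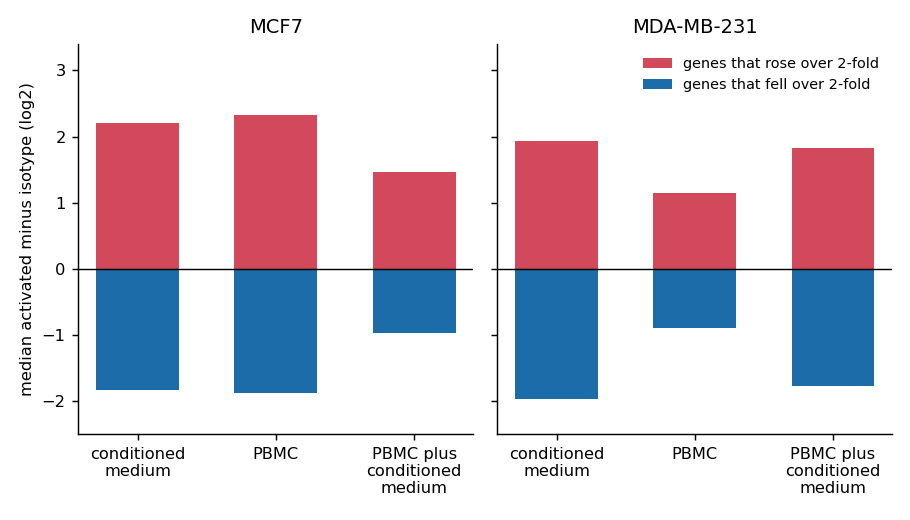
Median activated minus isotype log2 change by exposure format in MCF7 and MDA-MB-231, for genes that rose (red) or fell (blue) over 2-fold with 1 sign in all 3 formats. Bars start at 0. The smallest median rise is 1.47 with PBMC plus conditioned medium in MCF7 and 1.15 with PBMC in MDA-MB-231.

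Blood cell transcripts were found in the MDA-MB-231 conditioned medium libraries. The activated one held 441 reads of IFNG, 264 of GZMB, 246 of IL2RA, 55 of CD2, 53 of CD3E and 20 of the B cell marker MS4A1, while the activated MDA-MB-231 library with PBMC behind the insert held 0 of each. The activated library with PBMC plus conditioned medium, which also received the medium, held 6 of IFNG, 6 of GZMB, 1 of IL2RA, 2 of CD2, 2 of CD3E and 0 of MS4A1. The isotype conditioned medium library held 12 reads of CD3E, 5 of CD2 and 8 of MS4A1, against 0 with PBMC. PTPRC had 396 reads in the activated conditioned medium library, 32 in the activated PBMC library, 142 in the isotype conditioned medium library and 63 in the isotype PBMC library.

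**Figure D4:**
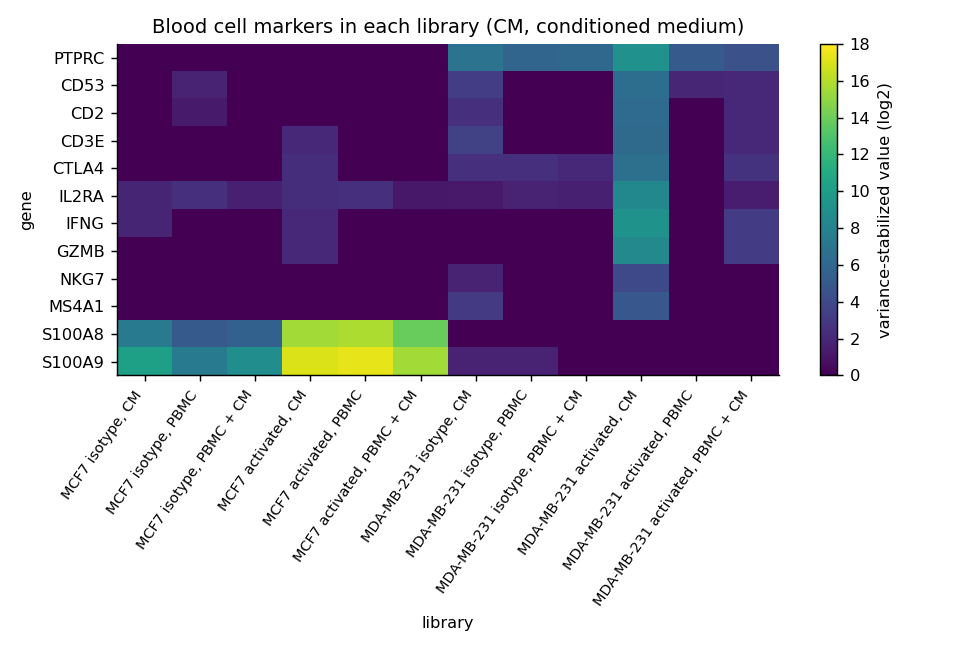
Variance-stabilized values (log2, colour scale) of blood cell markers (rows) in the 12 libraries (columns). T cell markers are highest in the activated MDA-MB-231 conditioned medium library (IFNG 9.23, GZMB 8.50), and S100A8 and S100A9 are high in the MCF7 libraries (means of 15.04 and 16.63 after activation).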

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

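The tests of explanations and the splits of the libraries were chosen after the results were seen; the comparison of the lines' responses was planned. The responses to activation differed between the lines in 2512 genes. Among 100 of the splits of the libraries within each line, the real one included, 1 gave a count this large, and the highest of the others was 77, but these splits break the format pairs of the model and carry the activation effect into its spread. Of the 32 splits that keep the pairs, 2 gave as many genes: the real one and the one that turns every pair of 1 line round, which adds the responses instead of subtracting them (7703, the highest other). The highest of the rest was 413. Since the turned-round split adds the responses of both lines, the share could hardly fall below 2 of 32, which is not under 0.05. Splits that swap only some pairs also carry the activation effect into the spread. These splits thus decide nothing about chance, which is not excluded. For the difference, 10 lists passed camera with a preset correlation, but 0 with an estimated one, and 72 of the 100 free splits gave as many and the highest other gave 17. With the pairs kept 19 of 32 gave as many (highest other 17). In both kinds of split, swapped libraries carry the activation effect into the contrast. The splits thus decide nothing about chance for the number of lists, which stays open.

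The lists that passed camera for the difference with a preset correlation, of which 0 passed with an estimated one (lowest adjusted p = 0.083), had median differences (MDA-MB-231 minus MCF7, log2) of -2.00 for interferon-gamma response, -2.10 for MHC class I, -3.62 for MHC class II, -2.15 for type I interferon genes, -0.66 for JAK-STAT, -0.78 for cell death, -1.69 for complement, -1 for hypoxia and glycolysis, -0.80 for cholesterol synthesis and -1.42 for monocyte markers. The single genes that differed most upward were IRG1 (7.99), SERPINB2 (7.07), SLAMF8 (6.94), KCNJ8 (6.59), ATP8A2 (5.57), SCG5 (5.48), RP11-13L2.4 (5.26), FAM20A (5.23), RP11-662G23.1 (5.23) and C10orf107 (5.18), and downward S100A7A (-10.14), S100A8 (-8.99), S100A9 (-8.95), S100A7 (-8.46) and TMEM98 (-8.37). KMO of the kynurenine pathway differed by -2.16. List members that differed were GBP1 (-5.55), CIITA (-4.72), NLRC5 (-4.97) and APOL6 (-3.94) for interferon-gamma, PSMB8 (-3.79), PSMB9 (-4.78) and ERAP2 (-4.18) for MHC class I, and HLA-DPA1 (-6.11), CD74 (-7.23) and HLA-DRA (-4.59) for MHC class II. Type I interferon genes included IFIT1 (-4.89), IFIT3 (-5.78), OAS2 (-4.61) and IFI44 (-6.96), and JAK-STAT genes STAT3 (-1.09), JAK1 (0.91), STAT1 (-0.93) and TYK2 (-0.76). Cell death genes were CASP10 (-3.90), BCL2L11 (-2.12), CASP7 (-1.50) and MLKL (-1.27), and complement genes C4A (-4.50), C1S (-2.62), C1R (-3.04) and C1RL (-3.57). The others were ADM (-2.46), ALDOC (-2.48), LDHA (-1.18) and PFKFB3 (-1.27) of hypoxia and glycolysis, DHCR24 (-1.65), MVD (-1.52), FDPS (-1.89) and HMGCS1 (-1.40) of cholesterol synthesis, and FCGR3A (-5.69) and ITGAM (-3.81) of the monocyte list.

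For the counts within 1 line, the 10 possible splits of 6 libraries are too few for a share under 0.05. Every other split also mixes activated and isotype libraries, which carries the activation effect into the spread. A low gene count in those splits was thus likely beforehand and decides nothing about chance. The real split gave 6506 genes in MCF7 and 4892 in MDA-MB-231 with 0 as the highest other in each, and 1 of the 10 splits was as large in each. The list counts were 17 in MCF7 (highest other 18; 3 of 10 splits as large) and 14 in MDA-MB-231 (highest other 15; 6 of 10). For the lines under isotype, with those 6 libraries fitted alone, the real split gave 13549 genes and the highest other 0 (1 of 10). There too the other splits mix the lines and carry their difference into the spread. For the formats, with the 8 libraries of each pair of formats fitted alone, all 32 splits gave at least the real count, which any split does where that count is 0, so the splits decide nothing about chance. The highest other was 0, 0 and, for PBMC plus conditioned medium against PBMC, 1320. A count this far above the real one points to a structure of those 8 libraries. It came from 2 splits, which put both MCF7 isotype libraries on 1 side. Both part the activated libraries with the weaker response from those with the stronger one. In this fit the 2 are the same contrast with opposite sign, in which the isotype libraries cancel. The other splits that part these activated libraries mix in isotype differences between formats and gave 0 genes. The structure is thus a difference between these activated libraries, and its cause stays open.

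Monocyte markers rose in MCF7, with S100A8 and S100A9 among the strongest changes of that line. A candidate source is blood monocytes in the MCF7 libraries, which would bring their other abundant transcripts. The rise of LYZ was 0.0382% of that of S100A8 (15 against 39188 normalized counts), and PTPRC, FCN1 and TYROBP together had 0 reads in the activated MCF7 libraries. Both values argue against monocytes. Expression by MCF7 itself, which the design names as the exposed line, stays open as a hypothesis, and contamination from outside the PBMC was not tested.

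T and B cell transcripts appeared in the MDA-MB-231 conditioned medium libraries. Carry-over of blood cells or their RNA with the medium is one candidate, and the values do not decide it. Of 59 genes in 7 blood cell lists with 3 reads or fewer in the activated PBMC library, 30 (50.8%) exceeded 3 reads in the activated conditioned medium library, against 3.0% of all other genes that low. This share measures the pattern and would be as high under induction. In the activated library with PBMC plus conditioned medium, which received the medium too, 13.6% of those list genes exceeded 3 reads (2.84% of other genes), with 6 reads of IFNG against 441, which argues against an equal carry-over wherever the medium went. In the activated conditioned medium library the share was 100% for T cell markers (12 genes) and pan-leukocyte markers (3 genes). It was 50% for NK cell and for B cell markers, and 42.9% for T cell cytokines. Monocyte markers had 22.2% and platelet and red cell markers 0%. Induction within MDA-MB-231 by activated medium is argued against by the isotype conditioned medium library, where 30.8% of list genes without reads in the isotype libraries with an insert had reads, against 6.64% of other genes. That covers markers present without activation and leaves IFNG and GZMB, with 0 reads there, open. Whether carry-over took place, and if so of cells or free RNA, stays open. So does why the MCF7 libraries with the same format hold 2 reads or fewer of IFNG, GZMB and CD3E.

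The response of MCF7 with PBMC plus conditioned medium was weaker than with either alone. If part of its RNA came from unstimulated MCF7 cells, all strongly induced genes would fall short by 1 amount, but over the 299 genes that rose over 16-fold the interquartile range of the shortfall was 3.62 times that between the other activated libraries (1.47 against 0.41 log2), with IDO1 at -4.44, CXCL10 at -1.67, TAP1 at -0.95 and CIITA at -0.04. A size factor set too high would shift rising and falling genes alike, but rising genes moved by -0.79 and falling genes by 1.00. A weaker stimulus in this well may account for it, and the format itself stays open, as 1 library per format cannot separate them.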

How the results depend on the processing

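Voom, the level of IDO1 after activation and the use of an added constant of 1 (the scale the design had foreseen) as an alternative were chosen after the data were seen; the other alternatives were planned. Over all alternatives, the results for named genes kept their direction and side of the threshold in 5291 cases, were weaker in 570, stronger in 39 and reversed in 15. The planned edgeR fit on recovered reads was not run, and voom on those reads took its place. The line differences were not run with each line alone. The design paired the activated and isotype libraries of each line by format, and without this block the counts were 6556, 4809 and 2547.

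Under quantile normalization, equal totals, both other filters, all added constants, voom and no format block, the gene counts stayed within 1.5 times of 6506 in MCF7 (5869 to 7450), 4892 in MDA-MB-231 (3941 to 5238) and 2512 for the difference (1687 to 3190). Each line fitted alone gave 3973 genes in MCF7 and 66 in MDA-MB-231. Both of these fits used 6 libraries, so the smaller number of libraries does not by itself explain the unlike drops. Their cause was not tested. A fold change of 2 as the null left 838, 235 and 196, and 5990 for the lines under isotype. An estimated correlation left 1, 1 and 0 lists, and for the difference fry called 7.

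Leaving out 1 format of 1 line, where the smaller group is assumed to vary like the others, gave 2075 to 7032 genes for MCF7, 562 to 5251 for MDA-MB-231, 447 to 3633 for the difference, and 0 to 137 for format dependence. The IDO1 response difference ranged from -2.98 to -0.75 and its level difference after activation from 2.44 to 4.98. Ranges with a change of sign were -0.01 to 1.11 for RAC2 in MCF7, -0.42 to 0.53 for KLRD1, -0.22 to 0.09 for CD22 and -0.49 to 0.05 for ITGA2B in MDA-MB-231, and for the difference -0.48 to 0.12 for AADAT, -1.22 to 0.21 for CD6 and -0.85 to 0.11 for KLRD1. Other reversals were KLRD1 in MDA-MB-231 (0.04 with quantile normalization, 0.00 with an added 5, 0.01 with voom), AFMID in MCF7 (-0.03 with equal totals), CSF2 in MCF7 (0.00 with each line alone and with no format block) and IDO1, whose response difference was 0.71 with an added 5. That constant raises the value of 0 reads, and for the others the cause was not tested.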

Other observations

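Gene families, defined by symbol, were counted in both lines without a test per family. The families given were chosen after the values were seen, from 19 looked at. Of 16 S100A genes tested, 10 rose and 1 fell in MCF7, with 4 rises and 1 fall in MDA-MB-231, and S100A12 followed S100A8 and S100A9 with a rise of 7.53 log2 in MCF7 and 0.00 in MDA-MB-231. The carcinoembryonic antigen family had 4 rises among 4 genes in MCF7 and 1 in MDA-MB-231, led by CEACAM1 (6.54 and 1.64). Mucin genes rose in 6 of 8 in MCF7, and in MDA-MB-231 had 2 rises and 1 fall. SERPINB genes, which encode intracellular protease inhibitors, had 5 rises among 9 in each line, with SERPINB7 (5.24) and SERPINB9 (3.88) the largest in MCF7, and SERPINB2 (7.07) and SERPINB4 (5.39) the largest in MDA-MB-231. Kruppel-like factor genes had 5 rises and 2 falls among 15 in MCF7 and 8 rises and 1 fall in MDA-MB-231, with 7 higher and 1 lower in MDA-MB-231 by the test of the difference per gene. Of 48 RPL and 31 RPS ribosomal protein genes 9 and 9 fell in MCF7 and 28 and 20 in MDA-MB-231. By the test of the difference 4 RPL genes were lower in MDA-MB-231 and 1 RPS gene higher, with median differences of -0.16 and -0.17. Their median changes in MDA-MB-231 were -0.33 and -0.34, close to the -0.32 of the reference genes. Whether scaling accounts for these falls was not tested. The viral RNA sensor TLR3 rose by 3.95 in MCF7 and 2.64 in MDA-MB-231.

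The tests of the following hypotheses were chosen after the results were seen. IDO1 fell short by more than most induced genes in MCF7 with PBMC plus conditioned medium: its shortfall ranked 6 of 299 genes that rose over 16-fold. If IDO1 depended more steeply on the strength of the stimulus than other genes, it would fall short by more than most of them in the weaker MDA-MB-231 format as well. With PBMC in MDA-MB-231 it fell short by less than most: its shortfall was -0.94 against a median of -1.47, and 70.1% of 87 genes fell short by at least as much. The prediction of a steeper dependence in both lines was thus not met. With 1 library per line, antibody and format, the strength of the stimulus cannot be separated from the format. The hypothesis therefore stays undecided. IDO1 started from 0 reads in MCF7 and not in MDA-MB-231, and whether promoter methylation, named in the series title, relates to this was not tested, as no methylation data were analysed here.

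Genes with even read numbers outnumbered their odd neighbours. The number of genes with 2 recovered reads was at least 1.397 times the geometric mean of those with 1 and 3 reads in each of the 12 libraries. This may reflect both mates of a fragment having been counted as reads. The number of independent fragments behind each value would then lie below the read numbers given. The floor of 3 reads, and with it the lower bounds on the folds of IDO1 and TNFAIP6, would then no longer hold. The labels do not state whether sequencing was paired.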
